A study of Mus musculus with 20 samples.

How the data were processed

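Total RNA of sorted mouse cells had been hybridised to Affymetrix arrays by the authors, with 5 samples each of muscle SP, muscle MP, bone marrow SP and bone marrow MP cells. The deposited values are signal intensity values on a linear scale, a value per probe set and array, which the authors had scaled so that the 2%-trimmed mean of every array is 1501 after rounding. The software, the summary of probes into probe sets and the background correction are not given in the sources used here. The lowest value was 0 and none was negative, so a background subtraction or a floor applied by the authors, which changes folds of dim genes, cannot be read from the values. Of 12488 probe sets, 66 were controls and were left out of the tests, leaving 12422. Of these 10833 carried a single gene symbol, 396 several and 1193 none, and 8251 genes were named. Symbols were checked by gene identifier against the RefSeq annotation of the mouse assembly GRCm38.p6, which matched 10839 probe sets and changed 0 symbols. That annotation served for names only, and no genome sequence was used.

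All settings that follow were chosen before the data were examined, except where stated. Array medians differed by 0.943 on the log2 scale, more than the tolerance of 0.10 set in advance, so the arrays were quantile normalized. Values below the 25th percentile of all values (105 signal, log2 6.71) were set to it, log2 values were taken, and probe sets above this floor on at least 5 of the 20 arrays were kept, 10310 in all (9095 with a single symbol, 7295 genes). Quantile normalization gives all arrays the same distribution, so it removes any overall difference in RNA content between the groups, and the floor shrinks folds of dim genes. The groups were fitted together with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation without trend or robust options. Tests were two-sided and adjusted by Benjamini-Hochberg over all probe sets tested, with a threshold of 0.05. Comparisons were SP against MP in each tissue, muscle against bone marrow in each population, and the difference between tissues in the SP against MP change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

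Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, lists of at least 4 measured genes, the brightest probe set per gene, list sizes counting the genes measured, and adjustment over the lists of a comparison. The 26 lists, written from textbook knowledge, were hematopoietic stem and progenitor cell genes, ABC transporters, endothelial markers, pericyte and smooth muscle markers, fibroblast and extracellular matrix markers, satellite cell and myogenic genes, muscle fibre genes, erythroid markers, granulocyte markers, monocyte and macrophage markers, B lineage markers, T and NK cell markers, megakaryocyte and platelet markers, DNA replication genes, mitosis genes, cell cycle inhibitors and quiescence genes, immediate early and stress genes, Notch pathway genes, BMP and TGF-beta pathway genes, Wnt pathway genes, interferon-stimulated genes, MHC class II genes, oxidative phosphorylation genes, ribosomal protein genes, Schwann cell and glial markers and adipocyte markers. A correlation estimated for each list replaced the preset value as an alternative, and for 61 of the 62 list calls it gave the highest adjusted p of the alternatives. Each list call of the main fit is therefore printed with that value. Control probe sets of GAPDH, beta-actin and spiked-in transcripts were compared between SP and MP arrays by exact two-sided permutation over 252 splits.

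Named genes were chosen by rule. In each of the first 4 comparisons these are the 8 largest rises and the 8 largest falls among probe sets with a single symbol, an adjusted p under 0.05 and no overlap between the values of the groups. The 5 largest differences each way were taken for the difference between tissues. Up to 4 members past the threshold were taken from each list described, and the 8 largest shared changes each way for SP against MP, ranked by the smaller of the 2 log2 changes. A set of transporter, stem cell, endothelial and muscle genes was named whatever its values. Probe sets whose names carry an s, f, g, r or i suffix can cross-hybridise with related sequences, which applies to Alas2, Blnk, Cavin2, Cd22, Ceacam10, Fcer1g, Gadd45b, Gzma, Igkv6-23, Junb, Kif22, Klra7, Meis1, Mpo, Myb, Pold2 and Socs3.

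Alternatives tried were no further normalization and median scaling of the arrays, floors at the 10th and 40th percentile, a pseudocount in place of the floor, no filter and a filter at the median, empirical Bayes with trend and robust options, array weights, a fit of only the groups compared, the replicate number as a block, each array left out in turn, an estimated inter-gene correlation and the mean over a gene's probe sets. A covariate for the GAPDH 3' to 5' ratio and a fit without the 3 arrays of highest ratio (muscle SP 1, bone marrow SP 4 and bone marrow SP 5) were added after the control probe sets had been seen. The method was tested on simulated data of the same size. For a muscle SP against MP contrast it recovered 63% of 100 probe sets simulated at a log2 change of 1 and 99% at 2, and called 8 unchanged ones. For the difference between tissues it recovered 17% and 88%. These rates need not hold for the arrays, where spread differed between groups and genes co-varied. Of 1508 genes with several probe sets, 3, 18, 12, 35 and 2 passed in both directions, in the order of the comparisons above.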

Results

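The data compared cells sorted from skeletal muscle and bone marrow of adult C57BL/10SnJ mice, an inbred laboratory strain. From each tissue a side population (SP) and a main population (MP) had been taken. Side population cells are a small fraction that keeps little of a DNA-binding Hoechst dye because membrane pumps of the ABC transporter family export it. In bone marrow this fraction is known to hold blood stem cells. Main population cells are those that keep the dye. RNA of 4 groups of 5 samples each was measured on 20 expression arrays, 10310 probe sets passed the filter, and these represent 7295 named genes. Array medians before normalization lay between 319 and 613 signal units, and the number of arrays limits the precision. Nothing in the labels says that the samples of a group came from separate animals or separate sorts, so every p-value here measures only the spread between these samples, which may be technical.

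The 20 arrays separated first by tissue and then by sorted population. Principal component 1 carried 60.9% of the variance and component 2 carried 11.8%. Median Pearson correlations between arrays of the same group, taken across probe sets, were 0.942 for muscle SP, 0.971 for muscle MP, 0.946 for bone marrow SP and 0.967 for bone marrow MP. Between SP and MP arrays the median was 0.934 in muscle and 0.888 in bone marrow. Between the tissues it was 0.788 for SP and 0.733 for MP arrays.

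**Figure D1:**
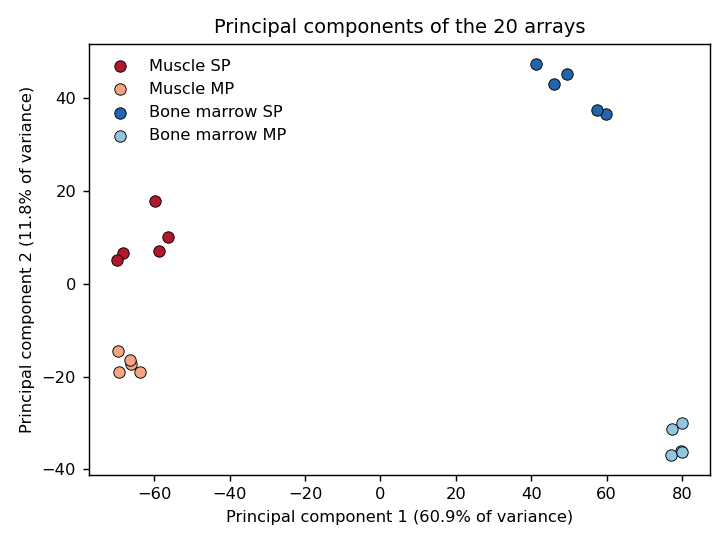
Principal components 1 (horizontal axis, 60.9% of variance) and 2 (vertical axis, 11.8%) of the log2 signals, without units, a point for each array coloured by group. The muscle arrays lie to the left of 0 and the bone marrow arrays to the right, and in both tissues the SP arrays lie above the MP arrays.

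Control probe sets on the arrays differed between SP and MP samples. The log2 ratio of the 3' to the 5' GAPDH probe set, which rises as RNA is degraded or amplified from the 3' end, was 3.83 ± 0.61 against 2.66 ± 0.62 (SD, n = 5) on muscle SP and MP arrays (exact two-sided permutation p = 0.0238, adjusted p = 0.0476 over 8 tests). In bone marrow it was 3.72 ± 0.60 against 2.67 ± 0.72 (exact permutation p = 0.0397, adjusted p = 0.0635), which did not pass. The beta-actin ratio was 2.52 ± 0.40 against 1.44 ± 0.43 in muscle (exact permutation, adjusted p = 0.0423) and 2.07 ± 0.72 against 0.98 ± 0.28 in bone marrow (exact permutation, adjusted p = 0.0317). Spiked-in control transcripts had mean log2 signals of 12.92 ± 0.51 against 11.97 ± 0.20 in muscle (exact permutation, adjusted p = 0.0317) and 12.79 ± 0.70 against 12.12 ± 0.30 in bone marrow (exact permutation, adjusted p = 0.127).

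The first comparison asked how muscle SP cells differ from the other cells of the same tissue. Muscle SP cells carried less RNA of fibroblast, myogenic and macrophage genes than muscle MP cells, and more of single genes such as Ccl5, Gzmb and Gzma. The chemokine gene Ccl5 was 37.8-fold higher in SP cells, at a mean log2 signal of 13.16 ± 2.05 (SD, n = 5) against 7.92 ± 0.47. Myf5, the transcription factor of muscle progenitors, was 10.5-fold lower, at 7.50 ± 0.61 against 10.89 ± 0.60. Of 10310 probe sets, 526 were higher in SP and 685 were lower (360 and 547 named genes), 236 and 415 of them by 2-fold or more. In what follows the brackets after a gene give its fold, its log2 difference ± standard error, or both, from 5 arrays per group. Where all arrays of the dimmer group lay at the signal floor, the change is a bound, written "at least" or, for a negative log2 value, "at most". List medians are of log2 changes, and counts of genes in a list are followed by those adjusted over the list alone where these differ.

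The largest rises in muscle SP cells were Ccl5 (37.8-fold, 5.24 ± 0.62, adjusted p = 5.7e-06), Gzmb (7.31-fold, 2.87 ± 0.42), Gzma (7.30-fold, 2.87 ± 0.39) and Selp (5.99-fold, 2.58 ± 0.39). Ccl5 is a chemokine of T cells, NK cells and platelets, Gzmb and Gzma encode granzymes, proteases of cytotoxic granules, and Selp encodes P-selectin of platelets and endothelium. Ifng (at least 2.49 ± 0.37), Klrd1 (at least 2.47 ± 0.40), Hdc (2.36 ± 0.21) and Lrg1 (2.28 ± 0.50) followed. Ifng encodes interferon gamma, Klrd1 an NK cell receptor chain, and Hdc the enzyme that makes histamine. The largest falls were C1qtnf3 (17.3-fold, -4.11 ± 0.28, adjusted p = 1.4e-09), H2-Aa (15.8-fold, -3.98 ± 0.59), Fgfr4 (13.4-fold, -3.74 ± 0.15) and Adcy2 (12.1-fold, -3.59 ± 0.26), followed by Calcr (-3.59 ± 0.18), Myf5 (-3.39 ± 0.26), Kera (-3.38 ± 0.29) and Gpm6b (-3.17 ± 0.46). H2-Aa encodes a chain of an antigen-presenting MHC class II molecule, Fgfr4 a growth factor receptor and Calcr the calcitonin receptor, both known from satellite cells, the stem cells of muscle, and Kera the matrix protein keratocan.

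Of 19 T and NK cell markers, 6 rose and 0 fell (7 and 0 adjusted over the list alone), median 0.57 (adjusted p = 4.2e-06, adjusted p = 0.197 with an estimated correlation). The members past the threshold were Ccl5, Gzmb, Gzma, Klrd1, Cd28 and Prf1, while Cd3e and Cd3g, parts of the T cell receptor complex, were at the floor on all muscle arrays. Of 30 interferon-stimulated genes, 7 rose and 0 fell (8 and 0), median 0.60 (adjusted p = 2.6e-06, adjusted p = 0.165 with an estimated correlation). Mx2 (3.05-fold, 1.61 ± 0.24), Iigp1 (2.43-fold, 1.28 ± 0.32) and Ifi47 (2.20-fold, 1.14 ± 0.22) rose most. Of 33 endothelial markers, 7 rose and 1 fell (12 and 1), median 0.40 (adjusted p = 2.3e-04, adjusted p = 0.0610 with an estimated correlation). Selp and Vwf (4.73-fold, 2.24 ± 0.44), the gene of von Willebrand factor, rose, whereas Lyve1 (5.34-fold, -2.42 ± 0.27) fell. Of 37 immediate early and stress genes, 6 rose and 1 fell (8 and 1), median 0.20 (adjusted p = 0.00915, adjusted p = 0.259 with an estimated correlation). The largest changes there were Nr4a2 (2.91-fold, 1.54 ± 0.30), Junb (2.60-fold, 1.38 ± 0.30) and Gadd45b (2.34-fold, 1.23 ± 0.25). These lists rose on arrays whose GAPDH 3' to 5' log2 ratio was 1.16 higher.

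Of 37 fibroblast and extracellular matrix markers, 19 fell and 2 rose (22 and 2), median -0.97 (adjusted p = 2.0e-11, adjusted p = 0.0158 with an estimated correlation). Serpinf1 (6.28-fold, -2.65 ± 0.42), Lum (5.21-fold, -2.38 ± 0.30) and Gsn (4.47-fold, -2.16 ± 0.25) fell most. Of 21 monocyte and macrophage markers, 11 fell and 0 rose (13 and 0), median -0.90 (adjusted p = 4.8e-08, adjusted p = 0.0358 with an estimated correlation). Mrc1 (7.81-fold, -2.96 ± 0.20), the mannose receptor, Lyz2 (7.41-fold, -2.89 ± 0.74), lysozyme, and Ctss (7.31-fold, -2.87 ± 0.55), cathepsin S, fell. The Lyz2 fold depended on single arrays and was 12.3 without muscle SP 2, 4.84 without muscle SP 4 and 4.83 without muscle SP 5, and its call was lost when only the groups compared were fitted (adjusted p = 0.102) or the GAPDH ratio was a covariate (0.0685, log2 -2.74 ± 0.93), a range of 6.6e-04 to 0.102. The Ctss fold was 4.73 without muscle SP 4.

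Of 24 satellite cell and myogenic genes, 10 fell and 0 rose, median -0.13 (adjusted p = 4.5e-07, adjusted p = 0.00856 with an estimated correlation). Fgfr4, Calcr and Myf5 fell, and Myod1, the factor of committed myoblasts, did not pass (-0.12 ± 0.19, adjusted p = 0.788). The median of this list was -0.28, -0.35 and -0.34 without muscle SP 1, 4 and 5 in turn, and the call held each time. Of 10 MHC class II genes, 4 fell and 0 rose (6 and 0), median -0.92 (adjusted p = 1.5e-04, adjusted p = 0.0718 with an estimated correlation), with H2-Ab1 (5.44-fold, -2.44 ± 0.41) and H2-Eb1 (4.51-fold, -2.17 ± 0.30) beside H2-Aa. Of 11 Schwann cell and glial markers, 4 fell and 0 rose, median -0.54 (adjusted p = 0.00309, adjusted p = 0.0718 with an estimated correlation), with Erbb3 (4.25-fold, -2.09 ± 0.34), Mal (3.67-fold, -1.88 ± 0.30) and Pmp22 (2.95-fold, -1.56 ± 0.37). These lists fell on arrays with the higher 3' to 5' ratios.

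Of 40 DNA replication genes, 7 fell and 0 rose, median -0.29 (adjusted p = 0.0265, adjusted p = 0.259 with an estimated correlation). Uhrf1 (3.07-fold, -1.62 ± 0.34), Pold2 (2.92-fold, -1.55 ± 0.43) and Pola1 (2.37-fold, -1.25 ± 0.33) fell. This list's call was also lost without muscle MP 3 (adjusted p = 0.0571), with a pseudocount (0.0594), with only the groups compared (0.0650) and with the mean over a gene's probe sets (0.124, median -0.13), a range of 0.00621 to 0.259. The Pola1 call was lost without muscle SP 3 (adjusted p = 0.0521, range 4.2e-05 to 0.0521) and the Pold2 call without muscle SP 5 (0.0595) and with only the groups compared (0.0513, range 0.00484 to 0.0595).

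The other lists did not pass in muscle. Of 18 Notch pathway genes 2 rose and 1 fell (3 and 1, adjusted p = 0.108). Of 22 B lineage markers 2 rose and 5 fell (3 and 7, adjusted p = 0.151). Of 28 hematopoietic stem and progenitor cell genes 3 rose and 1 fell (4 and 1, adjusted p = 0.294). Of 28 granulocyte markers 0 rose and 1 fell (adjusted p = 0.313). Of 30 Wnt pathway genes 1 rose and 4 fell (1 and 5, adjusted p = 0.392). Of 13 adipocyte markers 2 rose and 1 fell (3 and 1, adjusted p = 0.392). Of 30 muscle fibre genes 0 rose and 3 fell (adjusted p = 0.431). Of 23 ABC transporters 1 rose and 1 fell (adjusted p = 0.431). Of 31 ribosomal protein genes 0 rose and 1 fell (adjusted p = 0.469). Of 36 mitosis genes 2 rose and 2 fell (adjusted p = 0.505). Of 9 megakaryocyte and platelet markers 2 rose and 1 fell (adjusted p = 0.526). Of 32 BMP and TGF-beta pathway genes 6 rose and 2 fell (6 and 5, adjusted p = 0.526). Of 21 erythroid markers 3 rose and 0 fell (3 and 1, adjusted p = 0.548). Of 16 pericyte and smooth muscle markers 1 rose and 2 fell (adjusted p = 0.963). Of 27 cell cycle inhibitors and quiescence genes 4 rose and 3 fell (5 and 4, adjusted p = 0.963). Of 55 oxidative phosphorylation genes 0 rose and 2 fell (0 and 0, adjusted p = 0.963). Median, mean and test differed in sign for pericyte and smooth muscle markers (median -0.01, mean 0.02, test up), cell cycle inhibitors and quiescence genes (median -0.10, mean -0.02, test up) and oxidative phosphorylation genes (median 0.05, mean -0.01, test up).

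**Figure D2:**
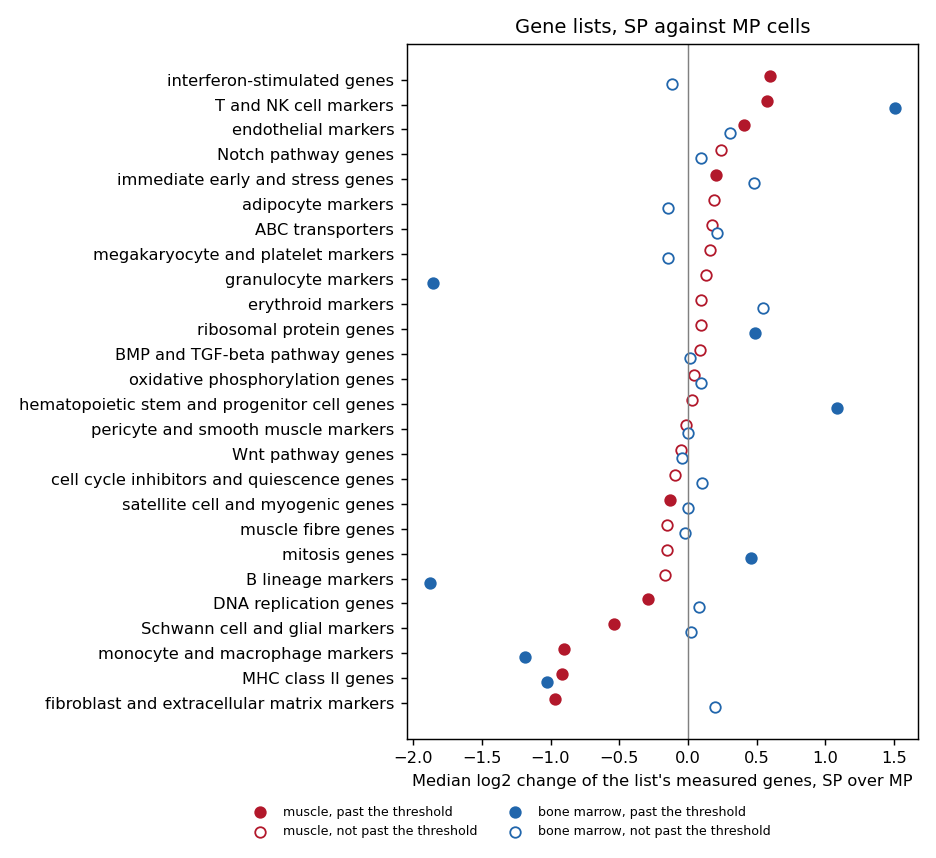
Median log2 change between SP and MP cells (horizontal axis, log2 units, positive when higher in SP) of the 26 gene lists (vertical axis), with a red point for muscle and a blue point for bone marrow, filled where the adjusted p of the list passed 0.05. T and NK cell markers had medians of 0.57 in muscle and 1.51 in bone marrow, and B lineage markers -0.17 and -1.88.

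The second comparison asked the same of bone marrow. Bone marrow SP cells carried more RNA of blood stem cell and ribosomal protein genes than MP cells, and less of B lineage genes. Meis1, a homeobox gene of blood stem cells, was 11.5-fold higher in SP cells (10.82 ± 0.75 against 7.29 ± 0.25, mean log2 signal ± SD, n = 5). Cd22, a receptor of B cells, was 10.2-fold lower (6.95 ± 0.24 against 10.29 ± 0.38). Of 10310 probe sets, 1583 were higher in SP and 1530 lower (1206 and 1084 named genes), 776 and 861 of them by 2-fold or more. The split of these calls moved with the scaling, since 50.9% were higher in SP after quantile normalization, 72.2% with no further normalization and 32.9% with median scaling, where the median log2 change of all probe sets was 0.02, 0.31 and -0.08.

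The largest rises were Ifng (50.6-fold, 5.66 ± 0.37, adjusted p = 2.4e-10), Thy1 (at least 43.6-fold, 5.45 ± 0.34), Slc1a4 (18.3-fold, 4.19 ± 0.21) and Ctla2b (17.3-fold, 4.11 ± 0.21), followed by Ccl5 (4.01 ± 0.62), Ctsw (at least 3.94 ± 0.36), Slc12a2 (3.91 ± 0.22) and Cdkn1c (3.91 ± 0.36). Thy1 is a surface protein of T cells and of some blood stem cells, Ctsw a cathepsin of cytotoxic lymphocytes, and Cdkn1c an inhibitor of cyclin-dependent kinases. The largest falls were Ceacam10 (26.2-fold, -4.71 ± 0.36, adjusted p = 2.1e-09), Il1rn (22.9-fold, -4.51 ± 0.40), Prg2 (22.2-fold, -4.47 ± 0.54) and Mfsd14b (18.7-fold, -4.23 ± 0.45), followed by Fcrla (-4.21 ± 0.26), Gsn (-4.01 ± 0.25), Ly6d (-3.90 ± 0.29) and Pla2g7 (-3.89 ± 0.25). Il1rn encodes the interleukin 1 receptor antagonist, Prg2 the major basic protein of eosinophils, and Fcrla and Ly6d are expressed in B lineage cells. The Prg2 fold was 34.5 without bone marrow SP 1.

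Of 28 hematopoietic stem and progenitor cell genes, 19 rose and 0 fell, median 1.09 (adjusted p = 2.9e-10, adjusted p = 0.00144 with an estimated correlation). Procr (10.3-fold, 3.37 ± 0.24) and Mllt3 (8.48-fold, 3.08 ± 0.22) rose with Meis1. Of 19 T and NK cell markers, 14 rose and 0 fell (16 and 0), median 1.51 (adjusted p = 2.3e-07, adjusted p = 0.191 with an estimated correlation). Cd3e (13.0-fold, 3.71 ± 0.23) and Cd3g (10.4-fold, 3.38 ± 0.37) rose there with Ccl5. Of 31 ribosomal protein genes, 16 rose and 0 fell, median 0.49 (adjusted p = 1.4e-05, adjusted p = 0.0127 with an estimated correlation), with Rpsa (3.36-fold, 1.75 ± 0.26), Rpl13a (2.98-fold, 1.57 ± 0.26) and Rpl22 (2.75-fold, 1.46 ± 0.26). The other Rpl22 probe set had a log2 change of -0.02. Of 36 mitosis genes, 11 rose and 1 fell (12 and 1), median 0.46 (adjusted p = 0.0228, adjusted p = 0.438 with an estimated correlation), with Kif22 (2.51-fold, 1.33 ± 0.19), Ttk (2.34-fold, 1.23 ± 0.22) and Tacc3 (2.08-fold, 1.06 ± 0.27). The SP arrays on which these lists rose had an actin 3' to 5' log2 ratio 1.09 higher.

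The mitosis call in bone marrow was lost without bone marrow SP 4 (adjusted p = 0.0514), with no further normalization (0.0559), with median scaling (0.0941), with a filter at the median (0.0678) and without the 3 arrays of highest GAPDH 3' to 5' ratio (0.0543), and its adjusted p over the alternatives ran from 0.00508 to 0.438.

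Of 22 B lineage markers, 20 fell and 0 rose, median -1.88 (adjusted p = 3.5e-15, adjusted p = 0.00883 with an estimated correlation). Bst1 (12.8-fold, -3.68 ± 0.25), Cd22 (10.2-fold, -3.35 ± 0.18) and Pou2af1 (9.95-fold, -3.32 ± 0.30) fell most. Of 28 granulocyte markers, 19 fell and 0 rose (21 and 0), median -1.85 (adjusted p = 3.3e-11, adjusted p = 0.110 with an estimated correlation), with Prg2, the oxidase gene Cybb (14.6-fold, -3.87 ± 0.43) and the eosinophil peroxidase gene Epx (10.8-fold, -3.43 ± 0.30). Of 21 monocyte and macrophage markers, 11 fell and 0 rose (13 and 0), median -1.18 (adjusted p = 4.1e-06, adjusted p = 0.0839 with an estimated correlation), with Adgre1 (6.21-fold, -2.64 ± 0.19), Mpeg1 (5.27-fold, -2.40 ± 0.37) and Cd14 (4.86-fold, -2.28 ± 0.26). Of 10 MHC class II genes, 6 fell and 0 rose (7 and 0), median -1.03 (adjusted p = 0.00665, adjusted p = 0.223 with an estimated correlation), with H2-Aa (7.48-fold, -2.90 ± 0.59), H2-Ab1 (5.85-fold, -2.55 ± 0.41) and H2-Ob (5.14-fold, -2.36 ± 0.38). The bone marrow SP arrays on which these genes fell had a GAPDH log2 ratio 1.05 higher, a difference that did not pass after adjustment.

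The remaining lists did not pass in bone marrow. Of 37 immediate early and stress genes 16 rose and 8 fell (17 and 8, adjusted p = 0.0769). Of 33 endothelial markers 10 rose and 5 fell (adjusted p = 0.0890). Of 21 erythroid markers 7 rose and 1 fell (8 and 1, adjusted p = 0.160). Of 13 adipocyte markers 1 rose and 5 fell (adjusted p = 0.179). Of 23 ABC transporters 6 rose and 1 fell (7 and 2, adjusted p = 0.239). Of 30 muscle fibre genes 1 rose and 4 fell (adjusted p = 0.352). Of 18 Notch pathway genes 6 rose and 2 fell (adjusted p = 0.428). Of 37 fibroblast and extracellular matrix markers 7 rose and 4 fell (7 and 3, adjusted p = 0.741). Of 32 BMP and TGF-beta pathway genes 7 rose and 2 fell (adjusted p = 0.741). Of 55 oxidative phosphorylation genes 10 rose and 2 fell (8 and 1, adjusted p = 0.762). Of 40 DNA replication genes 7 rose and 3 fell (6 and 3, adjusted p = 0.784). Of 30 interferon-stimulated genes 6 rose and 6 fell (9 and 8, adjusted p = 0.901). Of 16 pericyte and smooth muscle markers 3 rose and 1 fell (adjusted p = 0.935). Of 9 megakaryocyte and platelet markers 2 rose and 1 fell (adjusted p = 0.982). Of 27 cell cycle inhibitors and quiescence genes 6 rose and 8 fell (adjusted p = 0.982). Of 24 satellite cell and myogenic genes 3 rose and 4 fell (adjusted p = 0.982). Of 30 Wnt pathway genes 2 rose and 2 fell (1 and 1, adjusted p = 0.982). Of 11 Schwann cell and glial markers 1 rose and 0 fell (adjusted p = 0.982). Median, mean and test differed in sign for satellite cell and myogenic genes (median 0.00, mean 0.004, test down), megakaryocyte and platelet markers (median -0.15, mean 0.28, test up), cell cycle inhibitors and quiescence genes (median 0.10, mean 0.15, test down) and Wnt pathway genes (median -0.04, mean 0.05, test up).

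Transporters and surface markers chosen before the data were examined were measured whatever their change. Abcg2, the dye-exporting pump of side population cells, was 1.80-fold higher in muscle SP than MP cells (0.85 ± 0.25, adjusted p = 0.0280) and 4.48-fold higher in bone marrow SP cells (2.16 ± 0.25, adjusted p = 7.3e-07). Its muscle call was lost without muscle SP 4 (adjusted p = 0.0710), muscle SP 5 (0.0789), muscle MP 1 (0.0528), muscle MP 2 (0.0580) or muscle MP 4 (0.0651), with median scaling (0.0571) and with the GAPDH ratio as a covariate (0.106, log2 0.83 ± 0.31), a range of 0.00368 to 0.106. The Abcg2 rise was larger in bone marrow, with a tissue difference of -1.31 ± 0.35 (adjusted p = 0.0104), and that call was lost with median scaling (0.0662) and without the 3 arrays of highest GAPDH ratio (0.0572), a range of 7.6e-04 to 0.0662. The related pump gene Abcb1b had log2 changes of -0.39 ± 0.30 in muscle (adjusted p = 0.465) and 1.50 ± 0.30 in bone marrow (adjusted p = 5.1e-04, lost with the floor at the 40th percentile at 0.170, range 1.5e-05 to 0.170). Abcb1a did not pass in muscle (0.64 ± 0.39, adjusted p = 0.334) or bone marrow (at least 0.85 ± 0.39, adjusted p = 0.108).

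In bone marrow SP cells Kit (2.11-fold, 1.07 ± 0.29), Cd34 (3.60-fold, 1.85 ± 0.25), Kdr (3.00-fold, 1.59 ± 0.25), Tek (at least 2.29-fold, 1.20 ± 0.26) and Gata2 (3.04-fold, 1.60 ± 0.29) rose, genes of blood stem and progenitor cells or of endothelium. The Kit call was lost with the GAPDH ratio as a covariate (adjusted p = 0.159, log2 0.59 ± 0.29, range 0.00107 to 0.159), and the Tek call with the floor at the 40th percentile (0.462, range 9.2e-06 to 0.462). In muscle none of these passed, with log2 changes of -0.49 ± 0.29 for Kit, -0.36 ± 0.25 for Cd34, -0.25 ± 0.25 for Kdr, 0.58 ± 0.26 for Tek and -0.04 ± 0.29 for Gata2. Meis1 had -0.15 ± 0.27, adjusted p = 0.817 in muscle. Ptprc, the pan-leukocyte antigen CD45, had 0.92 ± 0.50, adjusted p = 0.268 in muscle and -0.61 ± 0.50, adjusted p = 0.405 in bone marrow. For Pecam1 the log2 changes were 0.30 ± 0.27 and 0.08 ± 0.27, and for Des, the muscle filament desmin, 0.34 ± 0.32 and -0.21 ± 0.32, none past the threshold. Myod1 did not pass in bone marrow (-0.08 ± 0.19, adjusted p = 0.815), and Myf5 was at the floor on all bone marrow arrays. Ly6a and Pax7 had no probe set assigned to them alone and were not analysed here.

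**Figure D3:**
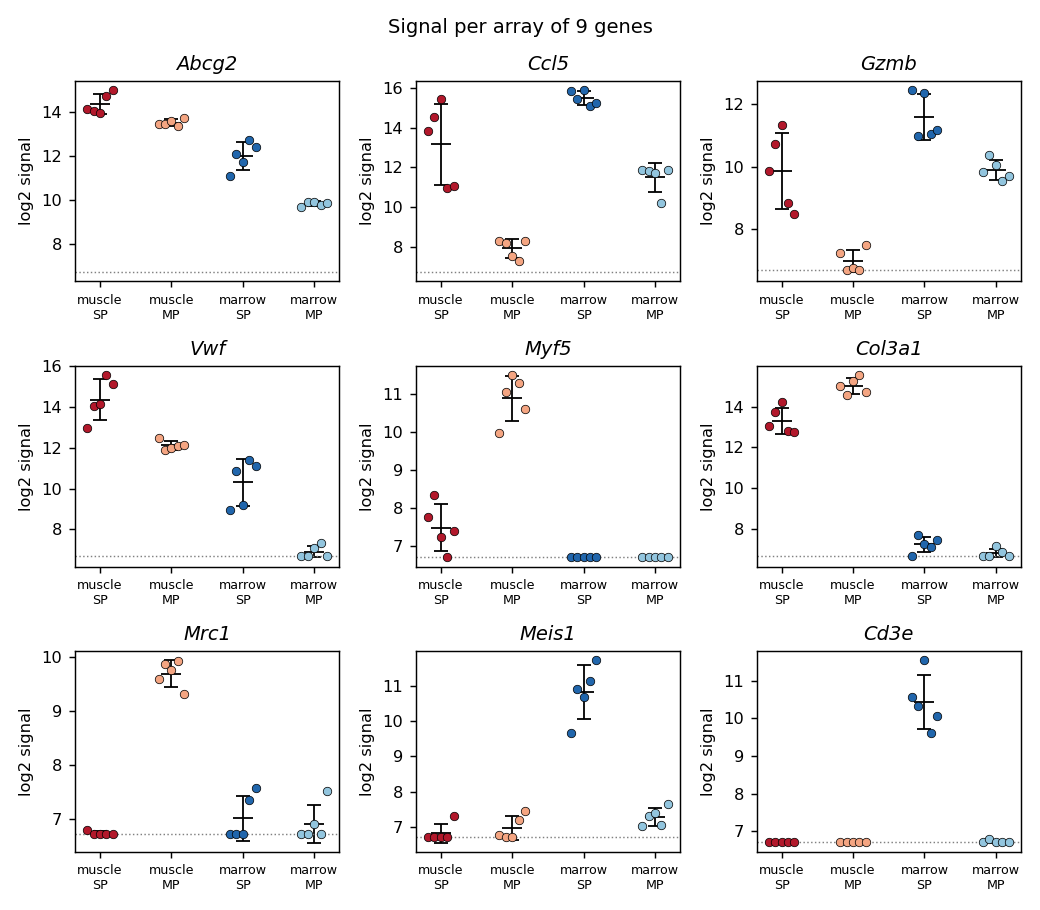
Log2 signal (vertical axes) of 9 genes in the 4 groups (horizontal axes), with a point per array, a bar at the mean of 5 arrays, whiskers of 1 SD and a dotted line at the floor of 6.71. Ccl5 averaged 13.16 in muscle SP and 7.92 in muscle MP cells, and 15.50 and 11.49 in bone marrow.

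Ccl5, Ifng, Klrd1, Gzmb and Vwf were higher in SP cells of both tissues, and H2-Aa, H2-Ab1 and Blnk were lower in both. Ccl5 rose 37.8-fold in muscle and 16.1-fold in bone marrow, Ifng at least 5.63-fold and 50.6-fold, Klrd1 at least 5.55-fold and 6.05-fold, Gzmb 7.31-fold and 3.26-fold, and Vwf 4.73-fold and 10.6-fold. The NK cell receptor gene Klra7 (1.77 ± 0.40 and 2.30 ± 0.40), the growth factor gene Vegfc (1.62 ± 0.25 and 2.16 ± 0.25) and the repressor gene Rest (1.81 ± 0.31 and 1.61 ± 0.31, log2 ± SE) also rose in both. Klra7 lost its muscle call with the floor at the 40th percentile (adjusted p = 0.168, range 7.9e-04 to 0.168).

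Among the shared falls, H2-Aa fell 15.8-fold in muscle and 7.48-fold in bone marrow, Ncam1, a cell adhesion molecule, 7.04-fold and 6.21-fold, Blnk, an adaptor of B cell receptor signalling, 6.17-fold and 6.07-fold, and Gsn 4.47-fold and 16.2-fold. H2-Ab1 (-2.44 ± 0.41 and -2.55 ± 0.41), Lyve1 (-2.42 ± 0.27 and -2.59 ± 0.27), the immunoglobulin gene Igkv6-23 (-2.38 ± 0.52 and -3.83 ± 0.52) and the tetraspanin gene Cd63 (-2.21 ± 0.32 and -2.13 ± 0.32, log2 ± SE) completed the named set. Igkv6-23 lost its muscle call with the GAPDH ratio as a covariate (adjusted p = 0.10, log2 -1.57 ± 0.58, range 4.2e-05 to 0.10), and its bone marrow fold was 8.90 without bone marrow SP 5.

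Higher in SP in both tissues were 196 probe sets (133 named genes) and lower 206 (156 genes), where independent lists would share 80.8 and 102. Opposite changes numbered 54 probe sets higher in muscle SP and lower in bone marrow SP (78.1 for independent lists) and 60 the other way (105). Across probe sets, which are not independent, the tissues' log2 changes had a Pearson r of 0.228, and 56.9% had the same sign. With median scaling the shared rises numbered 127, against 44.8 for independent lists.

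**Figure D4:**
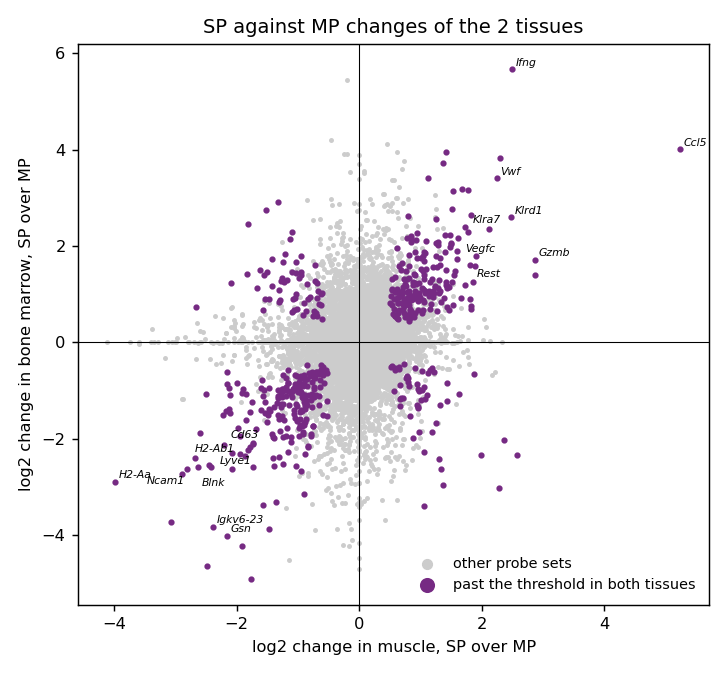
Log2 change between SP and MP cells in muscle (horizontal axis) and bone marrow (vertical axis), with a point per probe set, purple where past the threshold in both tissues and grey otherwise. Of the purple points, 196 lie to the upper right and 206 to the lower left.

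Whether the SP against MP change itself differed between the tissues was tested as an interaction, muscle minus bone marrow. Blood stem cell genes rose more in bone marrow, and B lineage genes, dimmer in muscle, fell more there. Myogenic genes, dim in bone marrow, fell more in muscle. The fold of a difference is the ratio of the SP to MP ratios of the tissues. The most negative differences were Thy1 (at least 50.1-fold, at most -5.65 ± 0.48, adjusted p = 5.0e-08), Slc1a4 (25.1-fold, -4.65 ± 0.29), F2rl3 (19.2-fold, -4.26 ± 0.78), F2r (19.1-fold, -4.26 ± 0.46) and Itm2a (18.9-fold, -4.24 ± 0.35). Thy1 was at the floor on all bone marrow MP arrays. The other F2r probe sets had differences of 0.14 and -0.05. The most positive were Lrg1 (39.3-fold, 5.30 ± 0.71, adjusted p = 1.7e-05), Selp (30.3-fold, 4.92 ± 0.55), Ceacam10 (26.2-fold, 4.71 ± 0.51), Prg2 (22.2-fold, 4.47 ± 0.77) and Bmx (21.9-fold, 4.45 ± 0.37). Ceacam10 and Prg2 were at the floor on all muscle arrays, so their differences are the bone marrow falls alone.

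In all, 1912 probe sets differed, 896 with a more positive and 1016 with a more negative change in muscle (638 and 825 named genes), 731 and 814 of them by 2-fold or more. The share that was more positive in muscle was 46.9% after quantile normalization, 30.4% with no further normalization, where the median of all probe sets was -0.23, and 62.2% with median scaling, where it was 0.13. Among fixed genes, Abcb1b (-1.90 ± 0.42), Kit (-1.57 ± 0.41), Cd34 (-2.20 ± 0.35), Kdr (-1.84 ± 0.35), Gata2 (-1.65 ± 0.41), Myf5 (-3.39 ± 0.37) and Meis1 (-3.67 ± 0.39) had differences past the threshold. The Abcb1b call was lost with the floor at the 40th percentile (adjusted p = 0.0977, range 2.3e-04 to 0.0977). No difference passed for Abcb1a (-0.21 ± 0.55), Ptprc (1.53 ± 0.70), Pecam1 (0.22 ± 0.38), Tek (-0.62 ± 0.37), Myod1 (-0.04 ± 0.27) or Des (0.55 ± 0.45).

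Of 28 granulocyte markers, 17 were more positive and 0 more negative (22 and 0), median 2.46 (adjusted p = 1.4e-11, adjusted p = 0.0786 with an estimated correlation). Of 22 B lineage markers, 15 were more positive and 0 more negative (18 and 0), median 1.69 (adjusted p = 1.7e-11, adjusted p = 0.0307 with an estimated correlation). Of 30 interferon-stimulated genes, 7 were more positive and 1 more negative (9 and 1), median 0.65 (adjusted p = 0.00249, adjusted p = 0.431 with an estimated correlation). Of 28 hematopoietic stem and progenitor cell genes, 14 were more negative and 1 more positive (15 and 1), median -0.99 (adjusted p = 9.1e-07, adjusted p = 0.0128 with an estimated correlation). Of 37 fibroblast and extracellular matrix markers, 20 were more negative and 2 more positive (21 and 3), median -1.41 (adjusted p = 1.1e-06, adjusted p = 0.0592 with an estimated correlation). Of 24 satellite cell and myogenic genes, 9 were more negative and 0 more positive, median -0.48 (adjusted p = 2.2e-04, adjusted p = 0.0307 with an estimated correlation). Of these 9, 3 were at the floor on all bone marrow arrays, as were 3 of those 17 granulocyte markers in muscle. Of 31 ribosomal protein genes, 9 were more negative and 0 more positive (16 and 0), median -0.52 (adjusted p = 0.00122, adjusted p = 0.0560 with an estimated correlation). The ribosomal call was lost with median scaling (adjusted p = 0.0928, range 6.0e-05 to 0.0928). Of 36 mitosis genes, 7 were more negative and 0 more positive, median -0.46 (adjusted p = 0.0118, adjusted p = 0.431 with an estimated correlation).

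The other lists did not pass for this difference. Of 11 Schwann cell and glial markers 0 were more positive and 4 more negative (adjusted p = 0.0589). Of 13 adipocyte markers 4 were more positive and 1 more negative (5 and 1, adjusted p = 0.0603). Of 40 DNA replication genes 0 were more positive and 7 more negative (adjusted p = 0.0815). Of 19 T and NK cell markers 0 were more positive and 4 more negative (adjusted p = 0.170). Of 21 erythroid markers 1 was more positive and 4 more negative (adjusted p = 0.410). Of 23 ABC transporters 1 was more positive and 3 more negative (1 and 4, adjusted p = 0.699). Of 30 Wnt pathway genes 1 was more positive and 3 more negative (adjusted p = 0.699). Of 30 muscle fibre genes 3 were more positive and 2 more negative (adjusted p = 0.919). Of 55 oxidative phosphorylation genes 0 were more positive and 5 more negative (0 and 1, adjusted p = 0.919). Of 9 megakaryocyte and platelet markers 1 was more positive and 1 more negative (adjusted p = 0.919). Of 37 immediate early and stress genes 7 were more positive and 7 more negative (9 and 9, adjusted p = 0.919). Of 27 cell cycle inhibitors and quiescence genes 5 were more positive and 4 more negative (8 and 5, adjusted p = 0.919). Of 32 BMP and TGF-beta pathway genes 3 were more positive and 2 more negative (adjusted p = 0.919). Of 33 endothelial markers 5 were more positive and 6 more negative (7 and 7, adjusted p = 0.919). Of 21 monocyte and macrophage markers 4 were more positive and 4 more negative (5 and 4, adjusted p = 0.919). Of 16 pericyte and smooth muscle markers 1 was more positive and 1 more negative (adjusted p = 0.978). Of 18 Notch pathway genes 1 was more positive and 3 more negative (adjusted p = 0.978). Of 10 MHC class II genes 0 were more positive and 1 more negative (adjusted p = 0.981). Median, mean and test differed in sign for cell cycle inhibitors and quiescence genes (median 0.00042, mean -0.17, test up) and Notch pathway genes (median -0.01, mean -0.06, test up).

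Muscle and bone marrow SP cells were also compared directly, to ask how far they share a profile. Muscle SP cells carried more RNA of endothelial, extracellular matrix and smooth muscle genes, and bone marrow SP cells more of mitosis and DNA replication genes. Cdh5, the cadherin of endothelial junctions, was 148-fold higher in muscle SP cells (14.49 ± 0.41 against 7.28 ± 1.05, mean log2 signal ± SD, n = 5). Myb, a transcription factor of blood progenitors, was 91.9-fold lower (8.32 ± 1.39 against 14.85 ± 0.17). Of 10310 probe sets, 1767 were higher in muscle SP and 2186 lower (1378 and 1632 named genes), 1250 and 1139 by 2-fold or more. The higher were 44.7% of these calls, 36.1% with no further normalization and 51.4% with median scaling, where the median log2 difference of all probe sets was -0.11, -0.27 and -0.07.

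The genes highest in muscle SP against bone marrow SP cells were Col1a2 (156-fold, 7.29 ± 0.29, adjusted p = 7.3e-15), Igfbp3 (150.5-fold, 7.23 ± 0.26), Cdh5 (148-fold, 7.21 ± 0.33) and Cav1 (146-fold, 7.19 ± 0.38), followed by Ackr3 (7.13 ± 0.17), Sparc (7.08 ± 0.33), Meox2 (at least 6.92 ± 0.16) and Kitl (6.92 ± 0.23). The other Col1a2 probe set had a log2 difference of -0.27. The lowest were Myb (91.9-fold, -6.52 ± 0.45, adjusted p = 7.2e-11), Mpo (74.0-fold, -6.21 ± 0.36), Ltf (51.6-fold, -5.69 ± 0.68) and Nfe2 (46.7-fold, -5.55 ± 0.29), followed by Ngp (-5.32 ± 1.07), Ltb (-5.26 ± 0.35), Lcn2 (-5.25 ± 0.57) and Mmp9 (-5.17 ± 0.48). Mpo, Ltf, Ngp, Lcn2 and Mmp9 are granule genes of neutrophils and their precursors. Without muscle SP 2 the folds were 82.0 for Ltf, 74.2 for Ngp and 60.3 for Lcn2. The Ngp fold was 21.6 without muscle SP 4 and 21.5 without muscle SP 5, and the Mmp9 fold was 55.0 without bone marrow SP 5.

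Of 33 endothelial markers, 28 were higher in muscle SP cells and 1 lower (29 and 1), median 3.46 (adjusted p = 3.6e-20, adjusted p = 7.1e-05 with an estimated correlation). Cdh5 and Cav1 led them. Of 37 fibroblast and extracellular matrix markers, 31 were higher and 0 lower (31 and 1), median 2.80 (adjusted p = 7.6e-19, adjusted p = 0.00112 with an estimated correlation). Of 16 pericyte and smooth muscle markers, 13 were higher and 1 lower (14 and 1), median 2.86 (adjusted p = 8.9e-09, adjusted p = 0.00299 with an estimated correlation), with Acta2 (6.88 ± 0.34) and Myh11 (6.13 ± 0.45). Of 37 immediate early and stress genes, 23 were higher and 1 lower (25 and 1), median 1.03 (adjusted p = 1.3e-07, adjusted p = 0.0169 with an estimated correlation), with Ccn1 (6.31 ± 0.24) and Socs3 (3.84 ± 0.17). Of 32 BMP and TGF-beta pathway genes, 18 were higher and 2 lower, median 1.02 (adjusted p = 8.1e-07, adjusted p = 2.9e-04 with an estimated correlation), with Tgfb2 (4.31 ± 0.20) and Ltbp4 (4.09 ± 0.24). Of 30 interferon-stimulated genes, 19 were higher and 2 lower, median 0.87 (adjusted p = 5.0e-05, adjusted p = 0.134 with an estimated correlation), with Iigp1 (4.03 ± 0.32) and Mx2 (3.23 ± 0.24).

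Of 13 adipocyte markers, 6 were higher in muscle SP cells and 1 lower, median 0.28 (adjusted p = 6.7e-04, adjusted p = 0.00645 with an estimated correlation), with Lpl (5.67 ± 0.32) and Cd36 (5.18 ± 0.16). The list median was between 0.93 and 1.02 when muscle SP 4, muscle MP 2 or bone marrow MP 2, 3 or 4 was left out. Of 30 muscle fibre genes, 10 were higher and 0 lower, median 0.39 (adjusted p = 0.00511, adjusted p = 0.134 with an estimated correlation), with Acta1 (4.09 ± 0.52) and Tpm1 (2.86 ± 0.25). Of 27 cell cycle inhibitors and quiescence genes, 14 were higher and 6 lower, median 0.46 (adjusted p = 0.0235, adjusted p = 0.167 with an estimated correlation), with Gas1 (4.16 ± 0.29) and Gas6 (3.64 ± 0.24). Of 24 satellite cell and myogenic genes, 9 were higher and 0 lower (10 and 0), median 0.32 (adjusted p = 0.0396, adjusted p = 0.134 with an estimated correlation), with Des (2.76 ± 0.32) and Vcam1 (2.45 ± 0.42). The myogenic call was lost with median scaling (adjusted p = 0.0911), without muscle SP 1 (0.0722, median 0.20), bone marrow SP 2 (0.0625) or bone marrow SP 4 (0.0603), or without the 3 arrays of highest GAPDH ratio (0.0725), a range of 0.00901 to 0.134. Of 18 Notch pathway genes, 8 were higher and 4 lower, median 0.33 (adjusted p = 0.0396, adjusted p = 0.0876 with an estimated correlation), with Notch3 (4.41 ± 0.38) and Dll1 (3.57 ± 0.40). That call was lost without muscle SP 1 (adjusted p = 0.0623), bone marrow SP 1 (0.0539) or bone marrow SP 4 (0.0571), with the replicate block (0.0530) and with the mean over a gene's probe sets (0.0676), a range of 0.0209 to 0.0876.

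Of 36 mitosis genes, 34 were lower in muscle SP cells and 0 higher, median -1.86 (adjusted p = 3.2e-15, adjusted p = 0.00299 with an estimated correlation). Mki67 (-3.47 ± 0.42) and Top2a (-3.43 ± 0.27) were among them. Of 40 DNA replication genes, 33 were lower and 0 higher (34 and 1), median -1.04 (adjusted p = 4.9e-10, adjusted p = 0.00299 with an estimated correlation), with Mcm5 (-3.19 ± 0.27) and Uhrf1 (-2.55 ± 0.34). Of 28 granulocyte markers, 24 were lower and 0 higher (26 and 0), median -3.19 (adjusted p = 3.1e-11, adjusted p = 0.0654 with an estimated correlation). Of 19 T and NK cell markers, 13 were lower and 0 higher, median -1.75 (adjusted p = 1.3e-04, adjusted p = 0.167 with an estimated correlation), with Cd3e (at most -3.72 ± 0.23) and Cd3g (at most -3.42 ± 0.37). Of 22 B lineage markers, 14 were lower and 1 higher (16 and 1), median -1.39 (adjusted p = 1.9e-04, adjusted p = 0.109 with an estimated correlation). Cd72 (8.11-fold, -3.02 ± 0.31) was lower and Ebf1 (9.39-fold, 3.23 ± 0.23), a factor of B cells and of fat cells, was higher.

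Of 21 erythroid markers, 10 were lower in muscle SP cells and 0 higher, median -0.56 (adjusted p = 2.6e-04, adjusted p = 0.0964 with an estimated correlation). Car2 (22.6-fold, -4.50 ± 0.21) and Nfe2 were among them, and the median was -0.86 without bone marrow SP 1. Of 21 monocyte and macrophage markers, 11 were lower and 0 higher, median -0.97 (adjusted p = 7.4e-04, adjusted p = 0.109 with an estimated correlation), with Lyz2 (-4.97 ± 0.74) and Mpeg1 (-3.95 ± 0.37). The Lyz2 fold was 52.1, 20.5 and 20.4 without muscle SP 2, 4 and 5 in turn, and its other probe set had a difference of 0.05. Of 31 ribosomal protein genes, 15 were lower and 0 higher (16 and 0), median -0.42 (adjusted p = 0.00556, adjusted p = 0.0736 with an estimated correlation), with Rpsa (-1.80 ± 0.26) and Rpl13a (-1.78 ± 0.26). Of 28 hematopoietic stem and progenitor cell genes, 16 were lower and 8 higher, median -0.76 (adjusted p = 0.0168, adjusted p = 0.108 with an estimated correlation), Myb among the lower and Tek (27.3-fold, 4.77 ± 0.26) among the higher genes. Of 10 MHC class II genes, 5 were lower and 0 higher, median -0.92 (adjusted p = 0.0199, adjusted p = 0.167 with an estimated correlation), with H2-DMa (-2.58 ± 0.27) and H2-Oa (-1.66 ± 0.25).

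Lists without a call in SP cells follow, as genes higher and lower in muscle. Of 55 oxidative phosphorylation genes 10 were higher and 1 lower (7 and 1, adjusted p = 0.132). Of 30 Wnt pathway genes 7 were higher and 2 lower (adjusted p = 0.171). Of 23 ABC transporters 8 were higher and 5 lower (10 and 6, adjusted p = 0.198). Of 11 Schwann cell and glial markers 4 were higher and 1 lower (5 and 1, adjusted p = 0.198). Of 9 megakaryocyte and platelet markers 2 were higher and 5 lower (adjusted p = 0.242). Median, mean and test differed in sign for ABC transporters (median -0.04, mean 0.47, test up) and Schwann cell and glial markers (median -0.06, mean 0.71, test up). Of the fixed genes, Abcg2 (2.37 ± 0.25), Abcb1a (4.89 ± 0.39), Abcb1b (1.61 ± 0.30), Cd34 (2.42 ± 0.25) and Kdr (4.78 ± 0.25) were higher in muscle SP cells, and Kit (-2.26 ± 0.29), Ptprc (-3.97 ± 0.50) and Meis1 (-3.99 ± 0.27) were lower. Myf5 (at least 1.72-fold, 0.79 ± 0.26) was higher in muscle SP cells, a call lost without muscle SP 2 (adjusted p = 0.0770), with the floor at the 40th percentile (0.819) and without the 3 arrays of highest GAPDH ratio (0.0884), a range of 4.7e-04 to 0.819. Pecam1 (-0.48 ± 0.27), Myod1 (0.08 ± 0.19) and Gata2 (-0.37 ± 0.29) did not pass.

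Muscle and bone marrow MP cells differed in 4795 probe sets, against 3953 for SP cells. Muscle MP cells carried more RNA of extracellular matrix, endothelial and smooth muscle genes, and bone marrow MP cells more of granulocyte and B lineage genes. Col3a1, a fibrillar collagen chain, was 287-fold higher in muscle MP cells (15.01 ± 0.40 against 6.85 ± 0.22, mean log2 signal ± SD, n = 5). Lcn2, a neutrophil granule protein, was 499-fold lower (6.98 ± 0.52 against 15.95 ± 0.13). Of 10310 probe sets, 2151 were higher in muscle MP and 2644 lower (1718 and 1853 named genes), 1513 and 1412 by 2-fold or more. The higher were 44.9% of these calls, 52.5% with no further normalization and 40.6% with median scaling, where the median log2 difference of all probe sets was -0.14, -0.05 and -0.20. Higher in muscle in both populations were 1318 probe sets (369 for independent lists), lower in both 1326 (561) and opposite 136, and the differences of both populations had a Pearson r of 0.805 across probe sets.

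The genes highest in muscle MP against bone marrow MP cells were Col1a2 (at least 496-fold, 8.95 ± 0.29, adjusted p = 1.5e-16), Sparc (at least 383-fold, 8.58 ± 0.33), Col4a1 (306-fold, 8.26 ± 0.30) and Cavin2 (295-fold, 8.20 ± 0.44), followed by Col3a1 (8.16 ± 0.26), Nrep (8.14 ± 0.30), Dcn (7.92 ± 0.27) and Aqp1 (7.89 ± 0.35). The other Col1a2 probe set had a log2 difference of -0.36 and the other Aqp1 probe set of -0.88. The lowest were Lcn2 (499-fold, -8.96 ± 0.57, adjusted p = 9.5e-12), Ltf (402-fold, -8.65 ± 0.68), Wfdc21 (296-fold, -8.21 ± 0.44) and Ngp (285-fold, -8.15 ± 1.07), followed by Mmp9 (-7.83 ± 0.48), Mmp8 (-7.76 ± 0.69), S100a9 (-7.66 ± 0.72) and Fpr2 (-7.40 ± 0.34), genes of neutrophils. The Ngp fold was 487 without muscle MP 2.

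Of 37 fibroblast and extracellular matrix markers, 32 were higher in muscle MP cells and 0 lower, median 4.14 (adjusted p = 2.3e-20, adjusted p = 7.2e-04 with an estimated correlation). Of 33 endothelial markers, 25 were higher and 2 lower (27 and 2), median 3.44 (adjusted p = 4.6e-14, adjusted p = 7.2e-04 with an estimated correlation). Aqp1 and Cav1 (7.88 ± 0.38) were among them. Of 16 pericyte and smooth muscle markers, 13 were higher and 0 lower (14 and 0), median 3.16 (adjusted p = 1.3e-07, adjusted p = 0.00730 with an estimated correlation), with Myh11 (at least 5.73 ± 0.45) and Kcnj8 (at least 5.42 ± 0.36). Of 32 BMP and TGF-beta pathway genes, 18 were higher and 2 lower (19 and 2), median 1.13 (adjusted p = 1.6e-05, adjusted p = 7.2e-04 with an estimated correlation), with Bmp6 (4.63 ± 0.24) and Tgfb2 (4.59 ± 0.20). Of 37 immediate early and stress genes, 23 were higher and 5 lower, median 1.20 (adjusted p = 4.0e-05, adjusted p = 0.0572 with an estimated correlation), with Ccn1 (at least 6.30 ± 0.24) and Socs3 (4.27 ± 0.17). Of 24 satellite cell and myogenic genes, 16 were higher and 1 lower, median 1.07 (adjusted p = 4.0e-05, adjusted p = 0.0118 with an estimated correlation), with Hey1 (4.30 ± 0.37) and Myf5 (at least 4.18 ± 0.26). Of 11 Schwann cell and glial markers, 6 were higher and 1 lower, median 1.38 (adjusted p = 0.0354, adjusted p = 0.179 with an estimated correlation), with Pmp22 (7.87 ± 0.37) and Egr2 (3.72 ± 0.27). This call was lost with the floor at the 10th percentile (adjusted p = 0.0517, median 0.54, range 0.00312 to 0.179).

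Of 28 granulocyte markers, 27 were lower in muscle MP cells and 0 higher, median -5.59 (adjusted p = 3.1e-17, adjusted p = 0.0197 with an estimated correlation). Of 22 B lineage markers, 21 were lower and 1 higher, median -2.96 (adjusted p = 3.5e-11, adjusted p = 0.0129 with an estimated correlation), with Cd72 (-4.67 ± 0.31) and Spib (-4.32 ± 0.41). The other Spib probe set had a difference of 0.93. Of 36 mitosis genes, 31 were lower and 0 higher, median -1.29 (adjusted p = 6.6e-09, adjusted p = 0.0197 with an estimated correlation), with Mki67 (-3.07 ± 0.42) and Cks2 (-3.01 ± 0.21). Of 40 DNA replication genes, 30 were lower and 3 higher (31 and 3), median -0.89 (adjusted p = 9.3e-06, adjusted p = 0.0197 with an estimated correlation), with Rrm2 (-2.26 ± 0.36) and Mcm10 (at most -2.24 ± 0.23). Of 21 monocyte and macrophage markers, 13 were lower and 3 higher (14 and 3), median -0.94 (adjusted p = 0.00747, adjusted p = 0.219 with an estimated correlation), with Tyrobp (-5.41 ± 0.57) and Fcer1g (-4.96 ± 0.35). Of 21 erythroid markers, 13 were lower and 2 higher, median -0.95 (adjusted p = 0.0141, adjusted p = 0.248 with an estimated correlation), with Nfe2 (-6.23 ± 0.29) and Car2 (-3.17 ± 0.21).

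Of 19 T and NK cell markers, 9 were lower in muscle MP cells and 1 higher (10 and 1), median -0.71 (adjusted p = 0.0331, adjusted p = 0.464 with an estimated correlation), with Ccl5 (-3.57 ± 0.62) and Gzmb (-2.91 ± 0.42). That call was lost with the floor at the 40th percentile (adjusted p = 0.137, median -0.22, range 0.00451 to 0.464). Of 10 MHC class II genes, 6 were lower and 0 higher, median -1.06 (adjusted p = 0.0391, adjusted p = 0.259 with an estimated correlation), with H2-Ob (-1.91 ± 0.38) and H2-Oa (-1.46 ± 0.25). This list lost its call with the floor at the 10th percentile (adjusted p = 0.0589) and a filter at the median (0.0679), a range of 0.0126 to 0.259. Lists without a call follow, as genes higher and lower in muscle. Of 30 muscle fibre genes 14 were higher and 4 lower (15 and 5, adjusted p = 0.0716). Of 55 oxidative phosphorylation genes 15 were higher and 3 lower (15 and 2, adjusted p = 0.102). Of 18 Notch pathway genes 8 were higher and 3 lower (adjusted p = 0.127). Of 30 Wnt pathway genes 11 were higher and 3 lower (11 and 4, adjusted p = 0.128). Of 13 adipocyte markers 4 were higher and 2 lower (adjusted p = 0.149). Of 30 interferon-stimulated genes 11 were higher and 6 lower (13 and 6, adjusted p = 0.167). Of 23 ABC transporters 7 were higher and 4 lower (adjusted p = 0.177). Of 27 cell cycle inhibitors and quiescence genes 11 were higher and 8 lower (11 and 9, adjusted p = 0.271). Of 9 megakaryocyte and platelet markers 2 were higher and 4 lower (3 and 5, adjusted p = 0.430). Of 28 hematopoietic stem and progenitor cell genes 12 were higher and 8 lower (12 and 9, adjusted p = 0.438). Of 31 ribosomal protein genes 2 were higher and 0 lower (adjusted p = 0.710). Median, mean and test differed in sign for adipocyte markers (median -0.05, mean 1.01, test up).

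Of the fixed genes, Abcg2 (3.69 ± 0.25), Abcb1a (at least 5.10 ± 0.39), Abcb1b (3.50 ± 0.30), Cd34 (4.62 ± 0.25), Kdr (6.62 ± 0.25) and Tek (at least 5.39 ± 0.26) were higher in muscle MP than bone marrow MP cells. Des (2.21 ± 0.32) and Gata2 (1.27 ± 0.29) were higher too, the other Gata2 probe set having a difference of -0.01, and Ptprc (-5.50 ± 0.50) was lower. Pecam1 (1.62-fold, -0.70 ± 0.27, adjusted p = 0.0397) was lower, a call lost without muscle MP 3 (adjusted p = 0.0793), MP 4 (0.103) or MP 5 (0.0932), without bone marrow MP 1 (0.0773) or MP 5 (0.106), with the floor at the 10th percentile (0.0531), no filter (0.0609) or no further normalization (0.0964), a range of 0.00365 to 0.106. Kit (-0.69 ± 0.29, adjusted p = 0.0559), Meis1 (-0.31 ± 0.27) and Myod1 (0.12 ± 0.19) did not pass.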

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

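The correlation test of lymphocyte genes across muscle SP arrays, the use of the GAPDH ratio as a covariate, its test over whole lists and the test of all stem cell genes above the floor were chosen only after the results were seen. The SP against MP change differed between muscle and bone marrow, by the interaction test, for 1912 probe sets and for the lists and named genes given here as log2 differences, muscle minus bone marrow. Lists with a negative median difference were hematopoietic stem and progenitor cell genes (-0.99), fibroblast and extracellular matrix markers (-1.41), satellite cell and myogenic genes (-0.48), mitosis genes (-0.46) and ribosomal protein genes (-0.52). Those with a positive median difference were granulocyte markers (2.46), B lineage markers (1.69) and interferon-stimulated genes (0.65). With an estimated correlation the fibroblast (0.0592), mitosis (0.431), ribosomal (0.0560), granulocyte (0.0786) and interferon (0.431) lists lost their calls, at these adjusted p-values. Of the 88 named genes that follow, 5 were at the floor on all 10 muscle arrays (Cd3e, Cd3g, Ceacam10, Epx and Prg2) and 4 on all 10 bone marrow arrays (C1qtnf3, Calcr, Fgfr4 and Myf5), so their difference is the change in the other tissue alone. A further 9, Thy1 among them, had a group with all arrays at the floor, so the size of their difference is limited by it.

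Stem cell, pump and vascular receptor genes with negative differences were Meis1 (-3.67), Procr (-2.80), Mllt3 (-2.68), Kit (-1.57), Cd34 (-2.20), Gata2 (-1.65), Abcg2 (-1.31), Abcb1b (-1.90) and Kdr (-1.84). Among lymphocyte genes there were Thy1 (-5.65), Cd3e (-3.71), Cd3g (-3.38), Ctsw (-3.32), Ifng (-3.17), Itm2a (-4.24) and Ctla2b (-3.66). The ribosomal and cell cycle genes were Rpl13a (-1.62), Rpl22 (-2.55), Rpsa (-1.84), Kif22 (-0.89), Ttk (-1.57), Top2a (-1.38), Mcm5 (-1.41) and Pold2 (-2.94). Transporters, receptors and regulators were Slc1a4 (-4.65), Slc12a2 (-4.11), F2r (-4.26), F2rl3 (-4.26), Cavin2 (-2.67), Cdkn1c (-4.15), Nr4a2 (-1.60) and Car2 (-1.33). Genes of the myogenic list or strongest in muscle MP cells were Myf5 (-3.39), Calcr (-3.59), Fgfr4 (-3.74), Hey1 (-2.98) and Adcy2 (-3.56). Connective tissue genes were Col1a2 (-1.67), Col3a1 (-2.13), Col4a1 (-3.44), Dcn (-1.41), Lum (-2.37), Serpinf1 (-3.05), Sparc (-1.50), Kera (-3.67), C1qtnf3 (-4.11), Nrep (-2.70) and Gas1 (-2.50). Glial, vascular and myeloid genes were Erbb3 (-2.79), Gpm6b (-2.84), Mal (-1.90), Pmp22 (-1.94), Egr2 (-1.73), Kcnj8 (-2.91), Aqp1 (-1.62), Bmp6 (-1.61), Mrc1 (-3.06) and H2-DMa (-1.20). Positive differences were found for the myeloid genes Ceacam10 (4.71), Prg2 (4.47), Epx (3.43), Cybb (3.51), Fpr2 (3.22), Il1rn (3.37), Lcn2 (3.72), Ltf (2.96), Mmp8 (2.98), Mmp9 (2.65), Wfdc21 (3.18), Fcer1g (2.38), Cd14 (1.12), Pla2g7 (2.41), Hdc (4.39) and Mfsd14b (2.33). They were also found for the B lineage genes Bst1 (4.11), Cd22 (3.12), Cd72 (1.65), Ebf1 (2.33), Fcrla (3.95), Ly6d (3.18), Pou2af1 (1.97) and Spib (2.67) and for Selp (4.92), Lrg1 (5.30), Bmx (4.45), Acta2 (3.32), Gsn (1.85) and Mx2 (1.47).

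Single arrays stood apart from the other 4 of their group for 37 of 567 group values tested (6.53%), where the gap to the nearest array divided by the group's range exceeded 0.71. Chance gives about 1 in 20 groups, and the values in brackets are these ratios. On bone marrow MP arrays these were Ebf1 (0.723), Ltf (0.734), Mki67 (0.725) and Ptprc (0.752) on array 2, Ccl5 (0.903), Cd14 (0.877), Pla2g7 (0.757), Procr (0.808) and Slc12a2 (0.815) on array 4. Array 5 gave Cd63 (0.864), Fcrla (0.872), Gsn (0.759) and Top2a (0.754). On bone marrow SP arrays these were Kdr (0.753), Nrep (0.743) and the mean of ribosomal protein genes (0.710) on array 1, Cav1 (0.780) and Pmp22 (0.892) on array 2. Array 5 gave Blnk (0.721), Hey1 (0.736), Mmp8 (0.730), Socs3 (0.881), Wfdc21 (0.715) and the mean of Notch pathway genes (0.851). On muscle MP arrays these were Ltbp4 (0.727) on array 1, H2-Eb1 (0.846) and the mean of granulocyte markers (0.722) on array 2. Others were Ctla2b (0.763) on array 3, Lyve1 (0.847), Nr4a2 (0.797), Pola1 (0.747) and the mean of muscle fibre genes (0.868) on array 5. On muscle SP arrays these were Mal (0.761) and Pou2af1 (0.764) on array 2, Ccn1 (0.897), Ctla2b (0.749) and the mean of ribosomal protein genes (0.929) on array 3.

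In each test only the real one of 100 array splits reached the real count. Splits that mix groups add spread, so no conclusion is drawn. For muscle SP against MP the real count was 1211 and the highest other 86, and for bone marrow 3113 and 743. Between the tissues they were 3953 and 1770 for SP cells and 4795 and 4 for MP cells. For the tissue difference they were 1912 and 195, and for shared rises 196 and 0.

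The first pattern weighed is the rise of T and NK cell markers in SP cells, whose call was lost in both tissues with an estimated correlation (adjusted p = 0.197 in muscle and 0.191 in bone marrow, ranges 3.7e-08 to 0.197 and 1.8e-09 to 0.191). RNA quality, which differed between SP and MP arrays, is argued against as the whole cause, because with the GAPDH 3' to 5' ratio as a covariate the list's median log2 change was 0.69 in muscle, against 0.57 without it, and 1.51 in bone marrow, against 1.51. Lymphocytes in varying number among the sorted muscle SP cells may contribute: the 6 risen members had a mean pairwise correlation of 0.823 over the 5 muscle SP arrays, above every random set of other risen genes (median 0.0152, highest 0.791). Hba-a1, Alas2 and the granulocyte, macrophage, muscle fibre and interferon-stimulated list means were also higher on muscle SP arrays 1 to 3 than on 4 and 5, so the pattern is not particular to lymphocyte genes. On muscle MP arrays Hba-a1 and Alas2 parted in the same way, whereas Ccl5, Ptprc and the T and NK list mean did not. On bone marrow SP arrays Ccl5 and that mean (9.78 on array 2, 9.76 on 5) did, but Gzmb, Gzma, Klrd1 and Prf1 did not. A difference shared by replicate number stays open for SP cells. Of the 6 members 2 (Ccl5 and Cd28) were above the floor on all muscle MP arrays and 0 were in another list. Mean log2 signals in muscle SP cells, which cannot be compared between probe sets, were 13.16 for Ccl5 and 9.85 for Gzmb, with Ptprc at 9.75. Cd3e and Cd3g were at the floor on all muscle arrays whereas Cd28, a T cell gene, rose, so T cells are neither shown nor excluded. The labels name no antibody gate that would remove lymphocytes, expression of these genes by side population cells themselves was not tested, and the explanation stays open.

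The next pattern is the fall of fibroblast, myogenic and macrophage markers in muscle SP cells. With the GAPDH ratio as a covariate the medians over all measured members were -0.85 (-0.97 without it) for fibroblast, -0.55 (-0.13 without it) for myogenic and -1.02 (-0.90 without it) for macrophage markers, and -0.85, against -0.82, for the 82 members together. All 3 calls held (adjusted p = 2.3e-09, 4.4e-07 and 5.3e-08), which argues against that ratio as the whole cause, leaving RNA quality open. The 40 members chosen because they fell had a median of -1.96 and 34 of them still passed. The others, Lyz2 among them, had larger standard errors. A lower share of these cell types among the sorted SP cells than among the MP cells may account for the fall and was not tested.

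The last pattern is the rise of blood stem cell genes in bone marrow SP cells, larger than in muscle by the interaction test. Signal below the floor in muscle is argued against for the 20 of 28 members above it on all 10 muscle arrays, taken whatever their bone marrow change. Their median log2 change was 1.40 in bone marrow and 0.03 in muscle, and the median difference was 1.21 (95% bootstrap interval over genes, which are not independent, 0.67 to 1.92). The 14 of them that rose in bone marrow, chosen for that rise, had a median difference of 1.61. For the other members, Meis1 among them, this stays open. Other muscle cells' signal could mask a change in the 20. A tissue difference in what the side population holds may account for the pattern and was not tested.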

How the results depend on the processing

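The GAPDH covariate and the fit without 3 arrays were chosen only after the control probe sets were seen. Of 230 named gene results past the threshold, 217 kept direction and side of the threshold under every alternative run, and of 62 list calls 26 did, 28 of the other 36 being lost with the estimated correlation alone. No called result turned direction. With no further normalization 2894 probe sets were higher in bone marrow SP than MP cells, and with median scaling 127 were higher in SP in both tissues. With an estimated correlation the lists past the threshold numbered 0 higher and 3 lower in muscle SP against MP, 2 and 1 in bone marrow, 6 and 2 for muscle against bone marrow SP, 4 lower for MP, and 1 and 2 for the tissue difference. Leaving out each array in turn gave 359 to 586 higher and 543 to 742 lower probe sets for muscle SP against MP (lists 4 to 4 and 5 to 6), and 1344 to 1687 and 1321 to 1621 for bone marrow (3 to 5 and 4 to 4). For muscle against bone marrow it gave 1632 to 1875 and 1951 to 2326 in SP cells (9 to 11 and 10 to 10) and 2018 to 2220 and 2351 to 2784 in MP cells (7 to 8 and 8 to 8). For the tissue difference it gave 774 to 965 and 872 to 1100 (3 to 4 and 5 to 6), with 143 to 227 shared rises and 163 to 240 shared falls. The fit of only the groups compared gives no value for the tissue difference.

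The groups share replicate numbers, and nothing states that these pair the samples. Of 10 arrays, the best match by residual correlation carried the same number for 1 in muscle, 2 in bone marrow, 5 between SP groups and 5 between MP groups. With the replicate number as a block, higher and lower probe sets were 487 and 646 (lists 4 and 6) for muscle SP against MP, 1567 and 1504 (lists 5 and 4) for bone marrow, 1854 and 2307 (lists 10 and 10) for muscle against bone marrow SP, 2227 and 2789 (lists 7 and 8) for MP and 882 and 999 (lists 3 and 5) for the tissue difference, with 190 shared rises and 184 shared falls.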

Other observations

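The genes and per-array values in this part were chosen only after their values were seen, and no test was added for them beyond the limma fit and a count of series. Genes of red cells did not all change in the same direction between the sorted populations. Of 21 erythroid markers in bone marrow 7 rose and 1 fell (median 0.55, adjusted p = 0.160). In bone marrow SP against MP cells Car2, carbonic anhydrase, rose (log2 2.27 ± 0.21, adjusted p = 4.6e-08), as did Slc4a1, the red cell anion exchanger (1.04 ± 0.34, adjusted p = 0.0226), whereas Epb42, a protein of the red cell skeleton, fell (-0.74 ± 0.15, adjusted p = 5.1e-04). Hba-a1, an alpha globin gene, did not pass (1.43 ± 0.61, adjusted p = 0.0844), nor did Alas2, an enzyme of heme synthesis (0.62 ± 0.66, adjusted p = 0.538). In muscle SP against MP cells Car2 rose (0.94 ± 0.21, adjusted p = 0.00461), while Hba-a1 (0.51 ± 0.61, adjusted p = 0.685) and Alas2 (0.10 ± 0.66, adjusted p = 0.966) did not pass.

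Several blood cell genes varied in level among the arrays of a group. On muscle SP arrays 1 to 5 the log2 signals of Hba-a1 were 14.04, 13.91, 13.38, 10.27 and 10.44, those of Alas2 were 10.89, 10.75, 9.87, 7.23 and 7.44, and those of Ptprc were 10.20, 10.70, 11.66, 7.58 and 8.59. For Ccl5 they were 13.81, 14.55, 15.43, 10.96 and 11.04. The mean log2 signals of the granulocyte list on the same arrays were 8.45, 9.34, 8.68, 7.71 and 7.63, and those of the monocyte and macrophage list 8.68, 8.69, 8.70, 7.84 and 7.89. The muscle fibre list had means of 9.16, 8.96, 9.14, 8.40 and 8.53 and the interferon-stimulated list 11.48, 11.59, 11.76, 11.25 and 11.17. Of these 9 series, with the T and NK list mean (8.56, 8.75, 9.29, 7.84 and 7.82), 9 had each of arrays 1 to 3 above both 4 and 5 in muscle SP cells, the group in which they were picked. It was 3 in muscle MP cells (Hba-a1, Alas2 and the muscle fibre list), 6 in bone marrow SP cells (all but Hba-a1, Ptprc and the macrophage list) and 0 in bone marrow MP cells. Chance gives 1 in 10 for a single series, and these are not independent.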
